A study of Mus musculus with 12 samples.

How the data were processed

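Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on fibro-adipogenic progenitors (FAPs), mesenchymal cells of skeletal muscle that can form adipocytes and matrix-producing fibroblasts. The cells came from muscle of mdx mice, which lack dystrophin and model Duchenne muscular dystrophy. Per the labels, young (1.5 months) and old (12 months) mice were injected into the peritoneum every day for 15 days with saline vehicle or with trichostatin A (TSA), an inhibitor of histone deacetylases, at 0.6 mg/kg/day, and muscle cells were sorted by flow cytometry; the sorting gate is not given in the sources used here. The marks were acetylation of histone H3 at lysine 27 (H3K27ac) and at lysines 9 and 14 (H3K9/14ac). The series has 12 samples, namely 8 immunoprecipitated and 4 input samples, with 1 library for each mark, age and treatment. The 4 input samples were not used here, and other assays that the design text names were not analysed here.

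The submitters' processing notes name Bowtie 0.12.7, DESeq2, HOMER, HTSeq 0.6.1p1, MACS2, TopHat2 2.0.9 and genome build GRCm38, without saying which step used which. Per the file headers, each of the 8 peak lists was written by HOMER's differential peak program, with the tag directory of a library set against itself. The values are therefore deposited per library, not pooled, and the whole-number tag count of each peak is not normalized, per the file headers. The fold ratio of target over background tags that the authors deposited is 1 for every peak of all 8 lists, and the deposited p-value lies between 0.502 and 0.531, so neither carries information on strength. The deposited peak score is 0 throughout, so that peaks were ranked by width where the plan had named the score. The total number of tags per library is not given in the sources used here.

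Each list as used here breaks off along the genome, inside 1 incomplete line, and 77135 complete peaks were read in all. The number of peaks in the whole list was taken from its header. Comparisons were restricted to the stretch that all 4 lists of a mark cover. For H3K27ac this was chromosomes 1 and 2 and chromosome 3 up to position 122275556, with 3788 protein-coding genes. For H3K9/14ac it was chromosome 1 and chromosome 2 up to position 167064301, with 2824 protein-coding genes. These stretches hold between 12.5% and 18.3% of the peaks counted in the headers. The old against young comparison under TSA was added after seeing the data, because both TSA lists reach further. It covered chromosomes 1 to 8 and chromosome 9 up to position 23224518 for H3K27ac (10942 genes), and chromosomes 1 to 3 and chromosome 4 up to position 155236417 for H3K9/14ac (5252 genes).

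Peaks of the lists of a mark were merged into regions where they overlapped by 1 bp or more or touched. A region was called gained or lost where it held a peak in 1 list and none in the other. Gene coordinates came from a RefSeq gene table of GRCm38.p6 with 21896 protein-coding genes. The table used here has neither strand nor exons, so that the planned promoter windows became gene ends, meaning 1000 bp either side of either annotated end, and positions were classed as gene end, inside a gene or outside. Acetylated length is the number of bp covered by peaks in a gene and 10000 bp either side. Relative tags are the log2 ratio of tags in that window minus the median log2 ratio over regions with a peak in every list. Peaks that cross a window's border gave tags in proportion to their overlap. Relative tags and this sharing out of tags were chosen after seeing the data; the errors printed with relative tags come from counting alone. A window can hold peaks of a neighbouring gene.

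The first 3 comparisons of each mark, most alternatives and 20 gene lists were fixed before the data were examined; the others are named as chosen after seeing the data. The lists cover FAP identity, fibrosis and matrix, adipogenesis, senescence and its secretory products, cell cycle, muscle stem cells, muscle fibres, macrophages, lymphocytes, endothelium, pericytes and smooth muscle, tenocytes, Schwann cells, immediate early genes, interferon response, Hox genes, acetylation enzymes and readers, Wnt, Notch and Hedgehog signalling, housekeeping genes, and neural genes as background. Of 493 symbols, 2 were not matched, and 489 genes remained. For each list the number of members with a marked gene end and the median difference in acetylated length were set among 10000 random lists of the same size. These were matched in 10 bins on the acetylated length summed over the mark's libraries. In the comparison of TSA libraries, and where labels were exchanged, only the compared libraries were summed. The percentile is given from 3 members upward. It describes these libraries and is not a p-value, since 1 library per group allows no test between groups. Lists of independent genes would put 5 in 100 percentiles outside the range 2.5 to 97.5, called the central range. Listed genes can share windows or vary together, and the comparisons share libraries. A list of mostly unmarked genes stays near the middle for length. The number of percentiles outside is therefore not calibrated.

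Genes were named by a rule. For each comparison these were the 5 largest gains and 5 largest losses of acetylated length for H3K27ac (3 and 3 for H3K9/14ac), leaving out predicted genes and genes whose window overlapped one already taken. From each list came up to 3 members with the largest difference in H3K27ac length and up to 3 whose gene end differed; further listed genes are given as members of their list. A few genes that the rule names are not reported here. Shares have exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. Intervals of correlations across regions came from 1000 resamples of 10-Mb blocks, and regions are not independent replicates.

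The alternatives were an overlap of at least 50% of each peak, the upper 50% of each list by width, lists of equal length by width or by tags, joining of peaks within 1000 bp, gene ends of 2500 bp, flanks of 2000 bp, random lists without matching, relative tags in place of length, and the stretch covered by both old lists. For some H3K9/14ac lists, values with the TSA and vehicle labels exchanged at 1 age were added after seeing the data. Equal list length by tags, relative tags, the stretch of both old lists and all alternatives of the comparison of TSA libraries were likewise added later. Tested on lists simulated from the young TSA list of each mark, with 4088 joined peaks for H3K27ac and 2487 for H3K9/14ac, the region step found 200 of 200 gained and 200 of 200 lost peaks for both marks. Peak calling was not simulated and the simulated gains lay away from other peaks, so full recovery was fixed by design. It checks the counting, not weak peaks near the calling limit. Of 200 unchanged gene lists drawn for each, with simulated independent differences in length, 186 and 191 lay inside the central range. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.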

Results

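Histone acetylation was profiled in FAPs of dystrophic mdx mice at an early (1.5 months) and a late (12 months) age, each after 15 days of TSA or of vehicle. The series concerns how far these progenitors still respond to deacetylase inhibition late in the disease. Each of the 8 combinations of mark, age and treatment had 1 library, so there are no replicates, and differences below are differences between single libraries. The headers counted 43021 H3K27ac peaks in the young vehicle library, 32874 in young TSA, 32062 in old vehicle and 41860 in old TSA. For H3K9/14ac the corresponding numbers were 21478, 26122, 25534 and 19869. In the stretches compared, peaks held 1659160, 1376021, 952786 and 1497491 H3K27ac tags and 452476, 631446, 608674 and 426273 H3K9/14ac tags, in the same order of libraries.

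**Figure D1:**
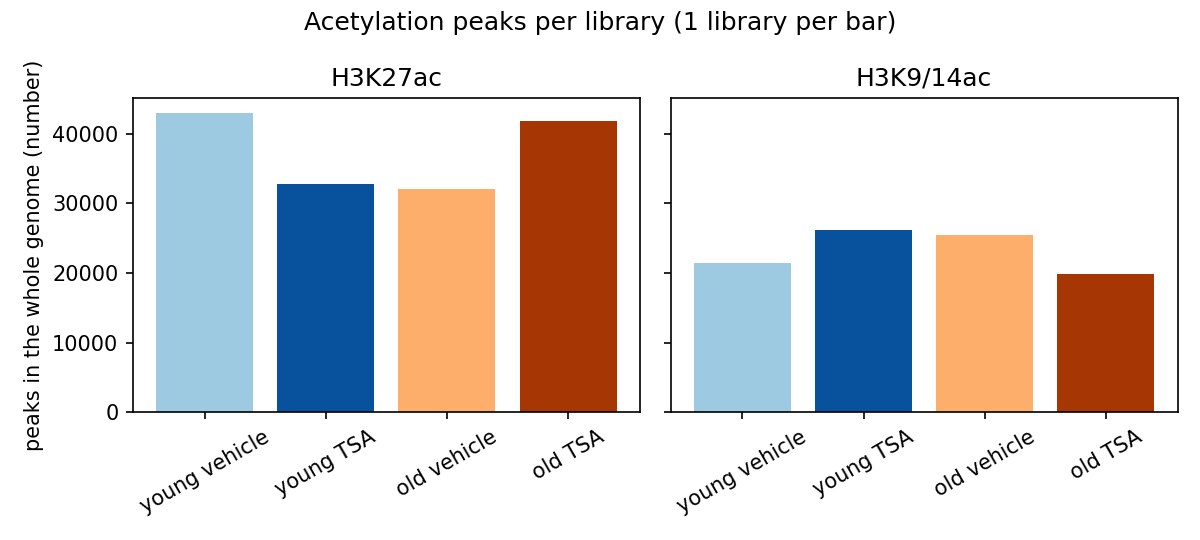
Number of peaks in the whole genome per library, from the list headers, for H3K27ac and H3K9/14ac; each bar is 1 library and has no error bar. H3K27ac peaks ranged from 32062 to 43021 and H3K9/14ac peaks from 19869 to 26122.

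The marks differed in where they lay. Gene ends held 63.3% (95% interval 61.5 to 65.2) of the H3K9/14ac peaks of the young vehicle library, against 29.3% (28.3 to 30.3) of its H3K27ac peaks. Of the H3K9/14ac peaks, 84.5% (83.1 to 85.8) overlapped an H3K27ac peak of the same condition in young vehicle, 70.1% (68.5 to 71.6) in young TSA, 67.1% (65.5 to 68.7) in old vehicle and 83.9% (82.4 to 85.3) in old TSA. Of the H3K27ac peaks, 34.8%, 51.4%, 49.5% and 39.2% overlapped an H3K9/14ac peak, in the same order. H3K27ac peaks compared numbered 5791, 4325, 4210 and 5564, and H3K9/14ac peaks 2711, 3336, 3235 and 2474. Both shares depend on these list lengths, so no difference between conditions can be read from them. Regions present in one library and missing in the other lay mostly away from gene ends. With TSA in young, 7.80% (6.76 to 8.94) of lost H3K27ac regions touched a gene end, against 41.0% (39.6 to 42.4) of shared regions. For H3K9/14ac gained with TSA in young, the share was 23.2% (20.7 to 26.0), against 72.1% (70.0 to 74.1) of shared regions.

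The first comparison asked how TSA and vehicle libraries of young FAPs differed in H3K27ac. Matrix genes were less covered with TSA: all 10 listed fibrosis and matrix genes had a shorter acetylated length, with a median of 10373.5 bp for vehicle and 4829.5 bp for TSA. Fbn1, which encodes the microfibril protein fibrillin-1 (chromosome 2, 125300594 to 125506485), was covered over 34376 bp with vehicle and 13667 bp with TSA, with relative tags of -0.98 ± 0.03 (log2). Col3a1, the gene of type III collagen (chromosome 1, 45311538 to 45349706), was covered over 20926 and 10176 bp, and Col5a2, a type V collagen chain, over 12936 and 3195 bp. Their relative tags were -0.90 ± 0.04 and -1.56 ± 0.06. The gene of periostin, Postn, a matrix protein of injured tissue, was covered over 3631 and 2043 bp.

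Among FAP identity genes, 4 of 5 were shorter with TSA. Prrx1, a homeobox transcription factor of limb mesenchyme, was covered over 21622 bp with vehicle and 9636 bp with TSA, and Cd34, a progenitor surface antigen, over 15291 and 10337 bp. Twist2 was the exception, with 2310 and 2363 bp. Endothelial genes held their coverage better than matched genes: Egfl7, a secreted vascular factor, was covered over 19433 and 20549 bp, and Sox18, an endothelial transcription factor, over 16089 and 15356 bp. The other large losses were at Fndc3b (chromosome 3, 27416135 to 27711307; 45905 to 23928 bp), Lhfp (33102 to 17627 bp), Celf2, an RNA-binding protein gene (35322 to 19856 bp), and Dnm3, a dynamin gene (39785 to 24347 bp). Gains were smaller, among them those at Nes, the nestin gene (4634 to 6616 bp), Il12a, a subunit of interleukin 12 (286 to 1846 bp), and Tspan2 (5369 to 6671 bp).

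Of 3788 genes, 1984 had a shorter and 359 a longer H3K27ac length with TSA in young, while marked gene ends numbered 1814 against 1851. There were 322 gained, 2410 lost and 4830 shared regions, and peaks covered 5.99 Mb against 8.04 Mb, with a median tag ratio of -0.12 (log2) in regions with a peak in every list. The matrix list stood at percentile 2.28 of matched random lists for length, with a median difference of -2526 bp, and at 0.110 for relative tags. With flanks of 2000 bp its length percentile was 10.8, and in the upper 50% of peaks by width it was 5. The endothelial list (2 of 4 members longer) stood at 98.1 for length, or 95.2 in the upper 50% by width, and at 99.6 for relative tags. FAP identity stood at 16.6 for length and 1.76 for relative tags.

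**Figure D2:**
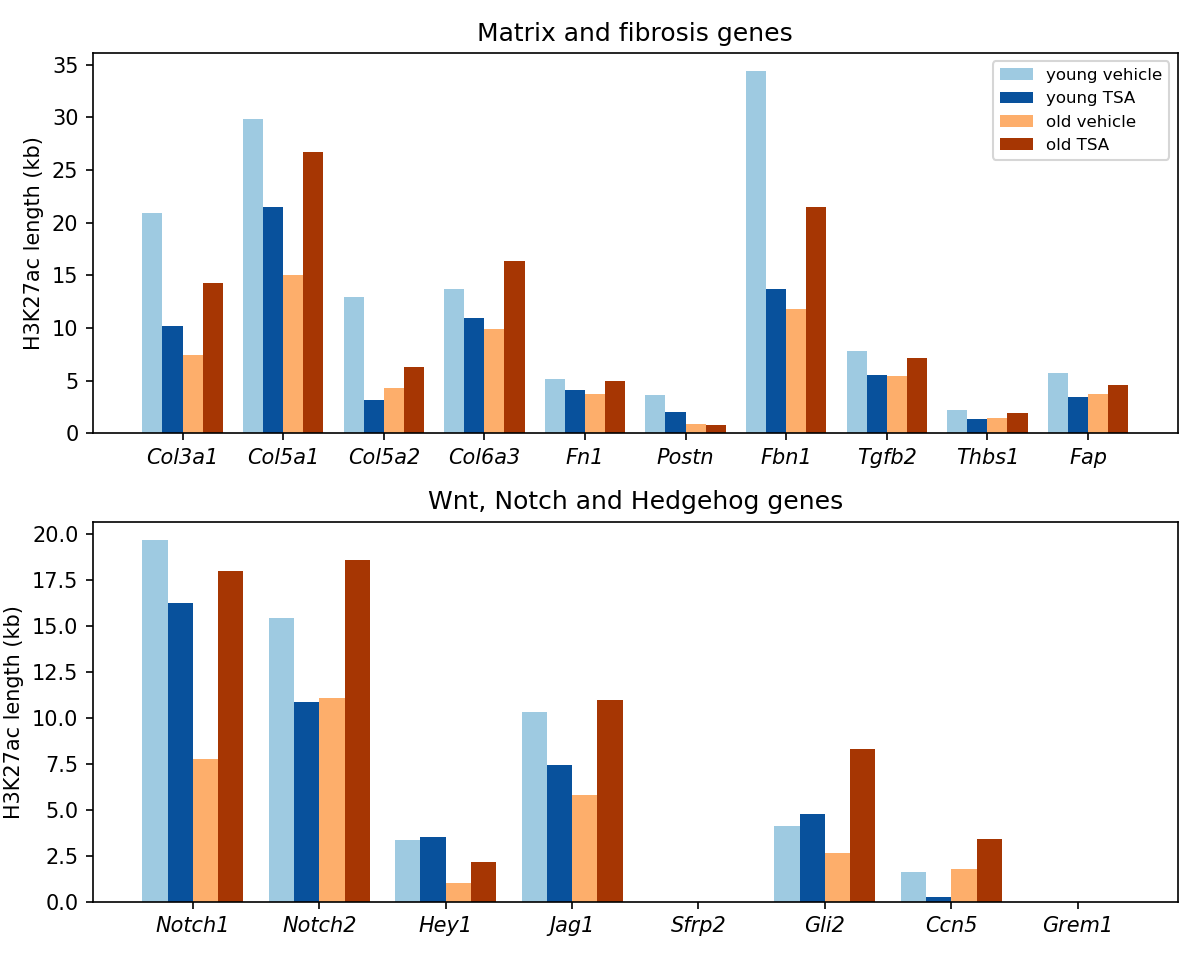
H3K27ac length (kb) in each gene and its flanks for listed matrix and fibrosis genes (upper panel) and Wnt, Notch and Hedgehog genes (lower panel) in the common stretch; each bar is 1 library, without error bars. Fbn1 was covered over 34.4 kb in young vehicle, 13.7 kb in young TSA, 11.8 kb in old vehicle and 21.4 kb in old TSA.

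H3K9/14ac of young FAPs, as labelled, covered more with TSA, 2.78 Mb against 2.33 Mb, yet 6 of 9 matrix genes were shorter. Their median difference was -634 bp, at percentile 0.025 of matched lists (2.89 in the upper 50% by width). An exchange of the H3K9/14ac labels at 1 age stays open below, and in young it would turn these directions. Col3a1 was covered over 1745 bp with vehicle and 356 bp with TSA (relative tags -2.87), and Fap, a serine protease gene of activated fibroblasts, over 1401 and 796 bp. Col5a1 went the other way, with 4133 and 5950 bp. The longest gains were at Tns1, the focal adhesion protein tensin 1 (7987 to 22280 bp), Rxra, a nuclear receptor gene (3869 to 12939 bp), and Niban2 (4291 to 12355 bp). The largest losses were at Fkbp7 (3371 to 981 bp), Tnfaip6 (1635 to 0 bp) and Hspa5, an endoplasmic reticulum chaperone gene (3280 to 1805 bp). Notch1 and Gli2, the Notch receptor and a transcription factor of Hedgehog signalling, were covered over 2667 and 9565 bp and over 1184 and 3801 bp, but Jag1 had 4263 and 4304 bp and Ccn5 365 and 397 bp, Grem1 had no peak, and their list stood at percentile 47.8 for length. In all, 1028 regions were gained, 264 lost and 1873 shared, and the median tag ratio of regions with a peak in every list was 0.40 (log2).

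The second comparison asked the same of old FAPs. Signalling genes stood out in H3K27ac: all 6 marked members of the Wnt, Notch and Hedgehog list were longer with TSA, and the other 2, Sfrp2 and Grem1, had no peak. Gli2 (chromosome 1, 118834061 to 119054405) was covered over 2680 bp with vehicle and 8312 bp with TSA, with relative tags of 1.26 ± 0.08. Notch1 was covered over 7750 and 17982 bp, Notch2 over 11064 and 18544 bp, and Jag1, a Notch ligand, over 5814 and 10970 bp. Gene ends of 3 of 6 senescence and secretory genes were marked with TSA and none with vehicle: Igfbp5, an insulin-like growth factor binding protein, Serpine2, a protease inhibitor, and Bmp2, a bone morphogenetic protein.

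Matrix genes were longer in 9 of 10 cases with TSA in old FAPs, as were most genes: Fbn1 was covered over 11828 and 21437 bp, Col5a1 over 15054 and 26732 bp, and Col3a1 over 7398 and 14283 bp. Postn was the exception, with 835 and 770 bp. All 5 FAP identity genes were longer, among them Prrx1 (11062 to 16817 bp) and Twist2 (978 to 2963 bp). All 4 endothelial genes were longer, such as Eng, a TGF-beta co-receptor (8329 to 15311 bp). In the Hox list, the 5 Hoxd genes from Hoxd3 to Hoxd10 were longer and 4 had no peak. The largest gains lay at Tns1 (chromosome 1, 73910232 to 74124548; 35852 to 57946 bp), Dab2ip, a Ras GTPase-activating protein gene (17082 to 35312 bp), Nav1 (30011 to 44559 bp), Tshz2 (24895 to 38045 bp) and Itpkb, an inositol kinase gene (31502 to 43882 bp). Losses were small, at Tnn (992 to 0 bp), Rbm39, a splicing factor gene (5138 to 4272 bp), the interferon-inducible Ifi205 (3606 to 2763 bp), Cp, which encodes ceruloplasmin (2439 to 1678 bp), and Snx21 (3301 to 2573 bp), whose window overlaps that of Tnnc2.

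Of 3788 genes, 2039 were longer and 297 shorter with TSA in old, with 1870 against 1679 marked gene ends. There were 2296 gained, 292 lost and 4182 shared regions, and peaks covered 6.90 against 4.82 Mb, with a median tag ratio of 0.50 (log2). The Wnt, Notch and Hedgehog list had a median difference of 3387 bp (percentile 99.95) and the senescence list stood at 99.95 for gene ends. For length the senescence list stood at 99.3, the endothelial list at 98.0, Hox at 99.7 and the matrix list at 85.3. By relative tags the senescence and endothelial lists stood at 65.1 and 92.6; with flanks of 2000 bp Hox stood at 50, and Hox windows overlap one another, which overstates that list's percentile.

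In the H3K9/14ac libraries labelled old TSA and old vehicle, signalling genes went the other way. All 4 marked members of the Wnt, Notch and Hedgehog list were shorter with TSA: Gli2 was covered over 4275 bp with vehicle and 2306 bp with TSA, Notch1 over 4515 and 3294 bp, and Ccn5, a matricellular protein gene of the Wnt pathway, over 1058 and 396 bp. Exchanging these labels would turn the sign of every such difference by construction, so it gives no evidence on whether the labels are right. All 3 endothelial genes were also shorter, such as Eng (3702 to 2676 bp), with 2 against 3 gene ends marked, at percentile 1.98 for gene ends (50.9 with gene ends of 2500 bp), 5.29 for length and 2 for relative tags. Neural genes, a background list, had 2 of 8 ends marked with TSA, Grin1 and Lhx2, and none with vehicle (98.92, or 94.99 with lists of equal length by tags). Col3a1 was covered over 160 and 1761 bp and Fap over 305 and 1069 bp, while Col5a1 had 6047 and 3909 bp. Of 9 matrix genes 6 were longer (percentile 92.0), and of all 2824 genes 1171 were longer and 700 shorter. By relative tags 3 of the 9 were higher and 6 lower (40.6). The longest gains were at Zeb2, a transcription factor of epithelial-mesenchymal transition (3567 to 9433 bp), Fam227b (1089 to 4356 bp) and Cacnb4, a calcium channel subunit gene (846 to 3923 bp). The largest losses were at Rxra (17883 to 6864 bp), Tns1 (22091 to 12036 bp) and Dab2ip (12871 to 6390 bp). There were 254 gained, 659 lost and 1934 shared regions. Peaks were fewer but wider with TSA, covering 2.55 against 2.42 Mb, and the median tag ratio was -0.47 (log2). The Wnt, Notch and Hedgehog list stood at percentile 1.16 for length (3.88 with lists of equal length by width) and FAP identity at 0.295 (95.5 in the upper 50% by width).

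Whether the ages responded at the same regions was examined with separate control libraries. For H3K27ac, 126 of the 322 regions gained with TSA in young were also gained in old, 39.1% (33.8 to 44.7). Independent lists would share 84.9 over all 8708 regions but 148 over the 5002 missing from at least 1 list, a base added after seeing the data, so that neither an excess nor a deficit can be read. With lists of equal length by width the share was 20.8%, against 17.6% and 34.8% for independent lists on these bases. For H3K9/14ac, 68 of 1028 were gained at both ages, 6.61% (5.17 to 8.31), where independent lists would share 71.1 or 133. In opposite directions, 195 of the 1028 gained in young were lost in old, 19.0% (16.6 to 21.5), against 185 or 345 for independent lists, and 29 of the 264 lost in young were gained in old (interval of the share 7.48% to 15.4%), against 18.3 or 34.2. For H3K27ac, 5 of the 322 gained in young were lost in old, against 10.8 or 18.8, and 514 of the 2410 lost in young were gained in old, against 635 or 1106. Lost at both ages were 105 H3K27ac regions, against 80.8 or 141, and 50 H3K9/14ac regions, against 47.4 or 88.7. Across the 3706 H3K27ac regions with a peak in every list, the TSA difference in young and in old had a Spearman correlation of 0.284 (0.245 to 0.327), and across 1709 H3K9/14ac regions it was -0.134 (-0.167 to -0.0946). Within each comparison, the marks' differences across 1338 regions correlated at 0.385 with TSA in young, -0.0871 with TSA in old, 0.237 in old against young vehicle and 0.235 in old against young TSA. Tags of the young and old vehicle and TSA libraries correlated most within an age for H3K27ac, 0.950 in young and 0.931 in old. For H3K9/14ac the highest value was 0.911, between young TSA and old vehicle, close to 0.909 between young vehicle and young TSA. The lowest was 0.879, between old vehicle and old TSA, and young and old vehicle also stood at 0.879.

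**Figure D3:**
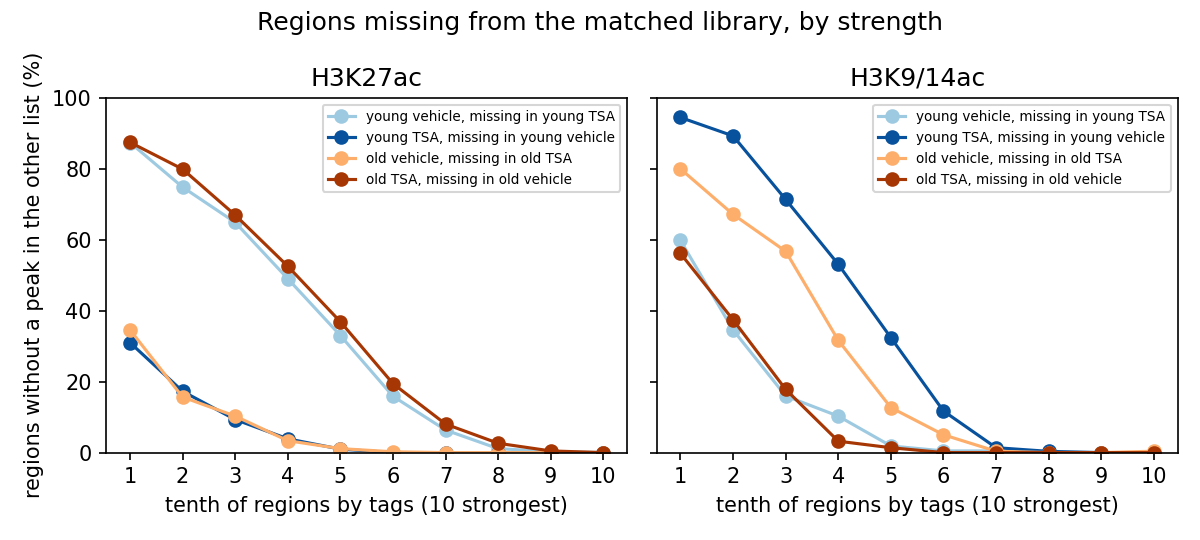
Percent of regions without a peak in the matched library (y axis) in 10 equal groups of the regions ranked by tags, 10 being the strongest (x axis), for TSA and vehicle libraries of the same age. In the weakest group, 87.4% of the young vehicle H3K27ac regions were missing in young TSA, and in the strongest group 0%.

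The third comparison set old against young vehicle libraries, to ask how FAP acetylation differed with age. All mice were mdx, so age cannot be told apart from disease stage. The comparison shares the young vehicle library with the first comparison and the old vehicle library with the second. Old vehicle had the fewest H3K27ac tags in peaks (952786), and the differences of these comparisons are not independent. Most genes had shorter H3K27ac in old FAPs, 2193 against 146 longer. The matrix genes were among them, with 10 of 10 shorter, though inside the central range of matched lists (percentile 7.74 for length and 8.58 for relative tags). Postn was covered over 3631 bp in young and 835 bp in old (relative tags -1.74), and Fbn1 over 34376 and 11828 bp. Endothelial genes were shorter in 4 of 4 cases, such as Eng (21408 to 8329 bp), and cell cycle genes in 7 of 8, such as E2f1, a transcription factor of S phase entry (2746 to 1077 bp). Gsn, which encodes the actin-severing protein gelsolin (chromosome 2, 35256359 to 35307902), was longer in old, with 12245 and 14696 bp and relative tags of 0.94 ± 0.05. Other gains were at S100a5 (9417 to 11884 bp), Plekha6 (1601 to 3749 bp), Aff3 (3717 to 5605 bp) and Eya2 (0 to 1669 bp). Besides Fbn1, the largest losses were at Fndc3b (45905 to 19145 bp), Rapgef2, a Rap exchange factor gene (42744 to 18484 bp), Rbms1 (47004 to 23040 bp) and Tshz2 (46855 to 24895 bp).

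Gene ends of the senescence list were marked in 2 young members, Igfbp5 and Serpine2, and in none of the old ones, at percentile 0.850 (11.6 with lists of equal length by width). The endothelial list stood at 6.56 and the cell cycle list at 8.38 for length, also inside the central range. Among other cell types, muscle fibre genes had 2 of 9 ends marked in young and 0 in old (percentile 1.46, or 3.64 without matching), Casq1 among them (6189 to 3903 bp). Macrophage genes had 0 of 6 in young and 1 in old, Spi1 (99.1, or 91.9 with lists of equal length by width), and Schwann cell genes 1 of 3 in young and 2 in old (99.6). With TSA in old, Schwann cell genes had 1 of 3 marked (0.350). In all there were 285 gained, 3051 lost and 4189 shared regions, 4.82 against 8.04 Mb covered and a median tag ratio of -0.61 (log2). H3K9/14ac was longer at FAP identity genes in 3 of 5 cases, led by Gsn (1165 to 7152 bp) and Twist2 (1016 to 2307 bp), at percentile 99.2 (95.9 in the upper 50% by width). Matrix genes were shorter in 7 of 9, among them Col3a1 (1745 to 160 bp) and Fap (1401 to 305 bp), at percentile 0.390 (8.68 in the upper 50% by width). This rests on the labels: the library labelled old TSA had 1761 bp at Col3a1 and 1069 bp at Fap. The list was not recomputed with labels exchanged. Gains were largest at Tns1 (7987 to 22091 bp), Rxra (3869 to 17883 bp) and Gsn, and losses at Fam227b (3650 to 1089 bp), Ssrp1, a histone chaperone gene (5685 to 3498 bp), and Ctnnd1, which encodes p120 catenin (3166 to 1038 bp). There were 718 gained, 262 lost and 1875 shared regions, 2.42 against 2.33 Mb covered and a median tag ratio of 0.34. Over these first 3 comparisons and both marks, 12 of 87 list percentiles for length lay outside the central range. For gene ends these were 8 of 87. Lists of independent genes would give 4.35, which is no calibrated base for an excess.

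A further comparison, added after seeing the data, set old against young TSA libraries over the longer stretch, with 10942 genes for H3K27ac. Fewer cell cycle genes were marked in old: 15 of 25 gene ends against 20, and 17 members were shorter. The gene end of Ccnd1, which encodes cyclin D1 (chromosome 7, 144929931 to 144939831), was among those marked only in young, with 1509 bp covered in young and none in old, as were those of Ccne1 and Ccne2, the cyclin E genes, Plk1, a mitotic kinase, and Cdc20, an activator of the anaphase-promoting complex. The Cdc20 window was nevertheless covered over 2714 and 2968 bp. Endothelial genes were shorter in 9 of 11 cases. Kdr, the VEGF receptor 2 gene (chromosome 5, 75932827 to 75979072), was covered over 9690 bp in young and 4565 bp in old, with relative tags of -1.18 ± 0.06, and Cdh5, the VE-cadherin gene, over 14306 and 8407 bp. Flt1 (12035 to 16196 bp) and Vwf (1543 to 1844 bp) were longer.

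Matrix genes were longer in old TSA than in young TSA FAPs in 12 of 15 cases, such as Eln, the elastin gene (1501 to 6783 bp), and Fbn1 (13667 to 21437 bp); Postn (2043 to 770 bp) and Tgfb1 (8007 to 7432 bp) were shorter and Tnc had no peak. In the Wnt, Notch and Hedgehog list 11 of 15 were longer, including Ccn5 (279 to 3411 bp) and Notch2 (10830 to 18544 bp), and Hey1 was shorter (3502 to 2174 bp). All 9 FAP identity genes were longer, led by Gsn (10426 to 18601 bp) and Prrx1 (9636 to 16817 bp). Senescence and secretory genes had 15 of 24 marked ends against 12, with Mmp2, a gelatinase gene, covered over 3154 and 7619 bp and Plaur, the urokinase receptor gene, over 595 and 1772 bp. Among all genes the gains were largest at Nfix (chromosome 8, 84704712 to 84801238; 49441 to 73985 bp), Tgfbr3, a TGF-beta co-receptor gene (30554 to 47374 bp), Nav1 (29369 to 44559 bp), Ahdc1 (15324 to 30092 bp) and Denn2b (33396 to 47357 bp). Losses were largest at Col4a2, a basement membrane collagen gene (49403 to 41260 bp), Rapgef2 (30189 to 23377 bp), Cdh5, Ppp1r16b (12393 to 6603 bp) and Frmd4a (23006 to 17673 bp).

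**Figure D4:**
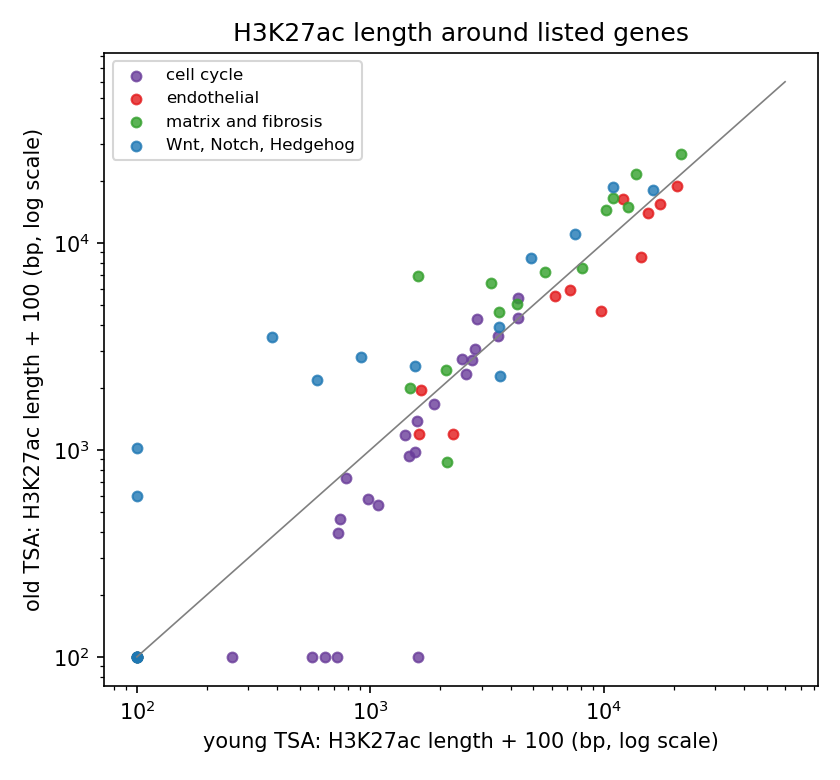
H3K27ac length (bp, plus an offset of 100 bp, log axes) of listed genes in the young TSA library (x axis) and the old TSA library (y axis); each point is 1 gene, the line marks equal length, and there are no error bars. Of the endothelial genes 9 of 11 lie below the line, and of the matrix and fibrosis genes 12 of 15 above it.

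In this added comparison the cell cycle list stood at percentile 0 for gene ends and 0.01 for length (49.9 in the upper 50% by width), and the endothelial list at 0 for length. The matrix list stood at 99.9 (92.6 with lists of equal length by tags), Wnt, Notch and Hedgehog at 100 (90.9 in the upper 50% by width), FAP identity at 81.4, and the senescence list at 98.8 for gene ends (87.5 with lists of equal length by width). Of 10942 genes, 3774 were longer and 2989 shorter in old, with 5725 gained, 1704 lost and 13271 shared regions and a median tag ratio of 0.04 (log2). The old TSA list was longer, and with equal list length by width the numbers gained and lost were 3002 and 2891. Equal list length brings these numbers close to each other by construction, so their balance gives no evidence on the cause.

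Among markers of other cell types, endothelial genes had 10 of 11 gene ends marked by H3K27ac in both TSA libraries, with a median covered length of 9690 bp in young and 5798 bp in old. Gene ends of the remaining lists of other cell types were mostly unmarked. Macrophage genes had 0 of 13 gene ends marked in young and 1 in old, that of Spi1, the PU.1 gene (0 and 1650 bp), while Ptprc, Itgam and the 3 C1q genes had no peak in either. Lymphocyte genes had 1 of 8 marked in both, and Cd2 was covered over 2725 and 4140 bp. In the muscle fibre list 4 of 18 ends were marked in young and 6 in old, with Tnnt3, a fast troponin gene, covered over 0 and 3221 bp; the list stood at percentile 97.6 for gene ends, but at 92.4 with lists of equal length by width, 92.5 by tags and 97.1 with gene ends of 2500 bp. Muscle stem cell genes had 5 of 11 marked in both, with Pax7 and Myod1 unmarked, and 6 were longer in old, such as Heyl, a Notch target (814 to 2707 bp) that the Wnt, Notch and Hedgehog list also holds. The muscle stem cell list stood at 99.9 for length, or 49.7 with lists of equal length by width and 45.8 in the upper 50% by width. Pericyte and smooth muscle genes had 1 of 5 marked in both, with Rgs5 at 688 and 1584 bp, at 99.3 for length and 50 in the upper 50% by width. Of the 2 tenocyte genes neither end was marked, and Fmod and Comp had 0 bp in young and 787 and 562 bp in old. Schwann cell genes had 1 of 4 marked, at percentile 50 for length, neural genes 0 of 12 in both libraries, and housekeeping genes 13 of 13 in both, at percentile 71.8 for length.

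H3K9/14ac in the same comparison showed 5 of 7 endothelial genes shorter in old, such as Eng (7149 to 2676 bp) and Sox18 (4775 to 2702 bp), at percentile 0.260 (4.62 in the upper 50% by width), with Tek (751 to 1341 bp) and Emcn (253 to 414 bp) longer. Cell cycle genes were shorter in 9 of 12, including E2f1 (3296 to 1434 bp) and Ccna2, the cyclin A2 gene (1179 to 475 bp), at percentile 6.23 for length and 0.900 for relative tags. The Wnt, Notch and Hedgehog list was shorter in 8 of 11, unlike in H3K27ac, with Notch1 at 9565 and 3294 bp and a percentile of 2.29 (2.67 with flanks of 2000 bp). This contrast depends in part on the labels. With TSA and vehicle exchanged in old, 3 of 11 members were longer and 5 shorter, with a median difference of 0 bp. The list then stood at 76.2 for length but 9.90 for relative tags. With them exchanged in young, only 5 members lay in the stretch, 3 longer and 1 shorter, at 59.0 for length. Gains were largest at Camk2d, a calcium-dependent kinase gene (3397 to 7331 bp), Zeb2 (6179 to 9433 bp) and Gask1b (2035 to 4672 bp). Losses were largest at Tns1 (22280 to 12036 bp), Hspg2, the perlecan gene (chromosome 4, 137468751 to 137570630; 22707 to 12600 bp), and Rgs3 (13633 to 6033 bp). Of 5252 genes, 1690 were longer and 1883 shorter, with 566 gained, 1930 lost and 3785 shared regions and a median tag ratio of -0.47 (log2). Across both marks, 10 of 36 list percentiles for length and 4 of 36 for gene ends lay outside the central range. Lists of independent genes would give 1.80, again no calibrated base for an excess.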

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

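All tests in this part were chosen only after the results had been seen. The number of H3K27ac peaks was lower with TSA than with vehicle in young FAPs (log2 ratio -0.39) and higher in old FAPs (0.38), and H3K9/14ac showed the opposite order, with 0.28 in young and -0.36 in old. These 4 values drew attention because the direction at one age opposed that at the other for each mark; the difference between ages was not tested, as each group had 1 library. An exchange of the TSA and vehicle libraries at 1 age would turn the sign of the correlation between the TSA differences of young and old across regions. For H3K27ac this correlation was 0.284, which argues against an exchange only if both ages respond at the same regions, and that was not tested. For H3K9/14ac the correlation was -0.134 and an exchange stays open, with no value here that decides it. A library-wide difference in enrichment, depth or peak calling also stays open: at least 91.4% of the regions missing from the shorter list were in the weaker 50% of the longer list, but so were at least 99.2% in the opposite direction, so this share does not separate the explanations. A response to TSA that differs with age remains possible and untested.

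The relative H3K9/14ac tags of the Wnt, Notch and Hedgehog list stood at percentile 99.6 with TSA in young FAPs and 0.200 in old. Each value rests on 4 genes, 3 of them higher with TSA in young and 0 in old. These opposite directions were not tested against each other. In old against young vehicle all 4 were higher (median 1.26, percentile 100). A difference between the vehicle libraries therefore stays open, as does an exchange of labels at 1 age.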

How the results depend on the processing

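Equal list length by tags, relative tags, the stretch of both old lists and every alternative of the old against young comparison under TSA were chosen after seeing the data; the others were planned. No paired analysis was possible because each group had 1 library. Of 158 list percentiles recomputed from values outside the central range, 108 stayed outside it and 50 moved inside, 5 of these across the middle. Of 922 recomputed from values inside it, 892 stayed inside and 30 moved outside, 3 of these across the middle. Of 1048 differences in length at named genes, 771 stayed within 1.5 times, 254 moved further and 23 reversed. Counts of regions depended on every choice, with 75 of 92 moved, and 33 of 50 shares and list totals moved. Fewer regions are found in shorter lists by construction; other causes were not tested. Tag counts limit the weak regions, where 1 library can miss a peak that the other calls.

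With an overlap of at least 50% of each peak, single peaks were counted, not merged regions. H3K27ac peaks then numbered 1726 gained and 3672 lost (TSA young) and 3863 gained and 2019 lost (TSA old). They numbered 2491 gained and 4655 lost (old against young vehicle) and 9192 gained and 4699 lost (old against young TSA). Single H3K9/14ac peaks numbered 1547 gained and 922 lost (TSA young) and 886 gained and 1647 lost (TSA old). They numbered 1365 gained and 841 lost (old against young vehicle) and 1662 gained and 3266 lost (old against young TSA). In the upper 50% by width, H3K27ac regions numbered 157 gained and 1144 lost (TSA young), 1135 gained and 152 lost (TSA old), 1468 lost (old against young vehicle), 2869 gained and 836 lost (old against young TSA). In the upper 50% by width, H3K9/14ac regions numbered 400 gained and 85 lost (TSA young), 136 gained (TSA old), 383 gained and 136 lost (old against young vehicle), 196 gained and 910 lost (old against young TSA). With equal list length by width, H3K27ac regions numbered 702 gained and 1078 lost (TSA young), 1222 gained and 606 lost (TSA old), 630 gained and 1542 lost (old against young vehicle), 3002 gained and 2891 lost (old against young TSA). With equal list length by width, H3K9/14ac regions numbered 495 gained (TSA young), 418 gained and 339 lost (TSA old), 425 gained (old against young vehicle), 845 lost (old against young TSA). With equal list length by tags, H3K27ac regions numbered 608 gained and 972 lost (TSA young), 1113 gained and 538 lost (TSA old), 565 gained and 1452 lost (old against young vehicle), 2713 gained and 2709 lost (old against young TSA). With equal list length by tags, H3K9/14ac regions numbered 448 gained (TSA young), 394 gained and 295 lost (TSA old), 379 gained (old against young vehicle), 774 lost (old against young TSA). With peaks within 1000 bp joined, H3K27ac regions numbered 1350 lost (TSA young), 1372 gained and 180 lost (TSA old), 170 gained and 1768 lost (old against young vehicle), 2966 gained and 988 lost (old against young TSA). With peaks within 1000 bp joined, H3K9/14ac regions numbered 147 lost (TSA young), 148 gained (TSA old), 160 lost (old against young vehicle), 315 gained (old against young TSA). On the stretch of both old lists, H3K27ac regions numbered 3893 gained and 535 lost (TSA old). On the stretch of both old lists, H3K9/14ac regions numbered 617 gained and 1336 lost (TSA old).

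The share of H3K27ac regions gained with TSA in young that were also gained in old was 20.8% with equal list length by width and 23.0% by tags, and that of H3K9/14ac 12.5% and 14.1%. Independent lists would give 17.6% and 16.5% for H3K27ac and 14.3% and 13.9% for H3K9/14ac over all regions, or 34.8%, 34.3%, 31.5% and 32.5% over regions missing from at least 1 list. With gene ends of 2500 bp, H3K27ac peaks at gene ends made up 35.1% (young vehicle), 41.9% (young TSA), 43.7% (old vehicle) and 37.7% (old TSA), and H3K9/14ac peaks 72.7%, 62.1%, 65.1% and 72.6%. In the upper 50% by width these shares were 38.5%, 45.9%, 45.2% and 40.4% for H3K27ac and 78.2%, 72.4%, 71.6% and 79.1% for H3K9/14ac. With at least 50% of the peak overlapped, H3K27ac peaks overlapped by H3K9/14ac made up 28.9%, 42.7%, 40.1% and 33.4%, and H3K9/14ac peaks overlapped by H3K27ac 81.7%, 66.3%, 61.4% and 78.1%, in the same order. In the upper 50% by width the first share was 38.5% in young vehicle and 54.5% in young TSA, and the second 71.7% in young TSA, 64.2% in old vehicle and 82.2% in old TSA. Lists outside the central range numbered 5 of 87 for gene ends with equal list length by width and 6 of 87 for length with flanks of 2000 bp. For old against young TSA they numbered 2 of 36 for gene ends of 2500 bp and 6 of 36 for length in the upper 50% by width.

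Reversed list percentiles were those of the endothelial list for H3K9/14ac gene ends of 2500 bp with TSA in old (50.9) and the immediate early list for H3K27ac with flanks of 2000 bp and TSA in young (46.5). The muscle stem cell list for H3K27ac in old against young TSA reversed with equal list length by width (49.7) and in the upper 50% by width (45.8), and FAP identity for H3K9/14ac with TSA in old in the upper 50% by width (95.5). The percentiles that moved outside across the middle were those of the Wnt, Notch and Hedgehog list with TSA in young, for H3K27ac in the upper 50% by width (38.6 to 97.9) and for H3K9/14ac with relative tags (47.8 to 99.6), and that of the Hox list for H3K9/14ac in old against young TSA in the upper 50% by width (7.72 to 98.3). Single H3K27ac lengths that reversed with flanks of 2000 bp differed by -586 bp at Atf3 and -22 bp at Il1a (TSA young), 706 bp at Cd2 and -36 bp at Ifih1 (TSA old), and -40 bp at Cd2 and 16 bp at Cebpb (old against young vehicle). With equal list length by width these were Fcer1g (-25 bp), Fcgr1 (-246 bp) and Ifih1 (-138 bp) with TSA in old and Lmod1 (419 bp) in old against young vehicle. By tags they were Ccn5 (279 bp) with TSA in young, Fcer1g (-25 bp) and Ifih1 (-561 bp) with TSA in old, and Lmod1 (419 bp) in old against young vehicle. In the upper 50% by width they were Hoxd3 (230 bp, TSA young) and Cd2 (191 bp, TSA old), with B2m (765 bp), Cebpb (32 bp) and Igfbp5 (8 bp) in old against young vehicle. In old against young TSA they were Casq1 (-519 bp), Ccnd2 (-257 bp), Rab7 (-215 bp) and Slc17a7 (-20 bp). The cause was not tested for any of these reversals.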

Other observations

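All tests in this part were chosen only after the results had been seen, and the comparison of the TSA libraries that they concern was added later. The following lists complete the account of old against young TSA libraries. Adipogenesis genes had longer H3K27ac in old in 10 of 16 cases, led by Klf15, a transcription factor of adipocyte metabolism (2044 to 5031 bp), with Pparg, the master regulator of adipocyte formation, at 3514 and 4573 bp. The 3 shorter members were Fabp4 at 7347 and 6472 bp, Cd36 at 5536 and 4605 bp and Cidec at 2047 and 1644 bp, while Lep, Plin1 and Pck1 had no peak. The list stood at percentile 74.5 for length and 99.1 for relative tags. In H3K9/14ac, 3 of its 5 members were longer, Fabp4 among them (974 to 1682 bp), and the list stood at 99.6 for length, or 60.4 in the upper 50% by width. Acetylation enzymes and readers had longer H3K27ac in old in 6 of 8 cases, such as Hdac4 (2065 to 4144 bp), Hdac11 (2409 to 4273 bp) and Ncoa3, a nuclear receptor coactivator (13577 to 18986 bp), at percentile 99.8 for length and 96.9 for relative tags. In old FAPs Hdac4 was longer with TSA than with vehicle (1782 to 4144 bp), but both comparisons use the same old TSA library and are not independent.

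Interferon response genes had 11 of 14 gene ends marked by H3K27ac in both TSA libraries and stood at percentile 56.4 for length, with the antiviral RNA sensor gene Ifih1 at 4073 and 6358 bp and Bst2, the tetherin gene, at 4495 and 2487 bp. Immediate early genes, which tissue dissociation can induce, had 12 of 12 ends marked in both and stood at 67.7, and Atf3 was covered over 1981 and 4467 bp. The Hox list stood at 23.6 in H3K27ac, with Hoxa3 at 16996 and 14983 bp and Hoxa10 at 16494 and 18403 bp. At the senescence locus, the gene end of Cdkn2b, a cell cycle inhibitor, was marked by H3K27ac only in old TSA (0 and 631 bp), while Cdkn2a, the p16 gene, had no H3K27ac peak in either. Cdkn2a was covered by H3K9/14ac over 717 bp in young and 1422 bp in old.

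The lower H3K27ac at endothelial genes in old TSA FAPs (9 of 11 shorter, with Kdr at 9690 and 4565 bp) was not removed by the different lengths of the lists, since with equal length by tags the list stood at percentile 0.01. A hypothesis is that the old TSA sample held a smaller share of endothelial cells, a type the sort may not remove fully. The H3K9/14ac libraries stood at percentile 0.300 for relative tags. With their TSA and vehicle labels exchanged they stood at 5.13 (in old) and 0.270 (in young, on 3 genes). By length the list lay below the central range with each labelling, though at 4.62 as labelled in the upper 50% by width. Shorter members were 5 of 7 as labelled, 6 of 7 with the exchange in old and 3 of 3 with that in young. The lower length in this mark therefore did not depend on these exchanges. Flt1 and Vwf had longer H3K27ac in old, and a smaller share of endothelial cells cannot be told apart from the other explanations here. Age without TSA went the same way in H3K27ac, with 4 of 4 endothelial genes shorter in old than in young vehicle FAPs. The list stood at percentile 6.56 for length and 4.02 for relative tags, and most genes were shorter (2193, against 146 longer). In H3K9/14ac as labelled, 2 of 3 were shorter and 1 longer, at 25.1 for length and 14.1 for relative tags. An effect of age stays open, as does a lower activity of these genes within FAPs, which was not tested. Against its own vehicle, old TSA had longer H3K27ac at 4 of 4 (98.0 and 92.6). Young TSA against vehicle stood at 98.1 and 99.6, with 2 of 4 longer, so a high young TSA library stays open too.

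The 5 cell cycle gene ends marked only in young TSA FAPs had weak peaks, the strongest at each holding 64 to 77 tags, against a median of 177 over the 20 marked members. The loss stood at percentile 0.01 among random lists matched in 50 bins on the tags of that peak, and relative H3K27ac tags were lower in 15 of 18 members with peaks in both (1.85), which goes against weak peaks alone; the length stood at 49.9 in the upper 50% by width, so they stay open. A smaller share of dividing cells in the old TSA sample is another candidate explanation that cannot be told apart here: relative H3K9/14ac tags of the list stood at percentile 0.900, but at 4.48 and 1.88 with the labels of that mark exchanged in old or in young. Mki67, a proliferation marker gene, had no H3K27ac peak in either library, and Ccnd2 (4214 to 5312 bp, though -257 bp in the upper 50% by width) and Cdt1 (2775 to 4198 bp) were longer in old. An effect of age or of TSA stays open too: 7 of 8 members were shorter in old than in young vehicle FAPs (percentile 8.38), while with TSA against vehicle in old 5 were longer and 2 shorter (25.3), ends marked were 6 against 5 (58.6), and 1 of 5 had higher relative tags (6.13).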
